A study of Danio rerio with 6 samples.

How the data were processed

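Transcript levels were measured by SYBR Green real-time PCR on array plates in zebrafish (Danio rerio) embryos at 24 hours post fertilization. Per the labels, embryos had been microinjected with the plasmid ptGFP1 (control) or with ptGFP1-NOD1 (NOD1), with 3 biological replicates in each group and 1 plate for each replicate. Total RNA had been extracted with TRIzol from 150 to 200 embryos per group on average, per the labels' protocols. Whether a replicate came from a separate spawning or injection session is not given in the sources used here.

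Each plate file held the threshold cycle (Ct) of 336 wells, with 326 wells for genes, 1 well per plate symbol, and 10 control wells. Each symbol is counted as a gene here, although some pairs of symbols map to the same zebrafish gene. The Ct is the cycle at which fluorescence crosses a threshold, so a lower Ct means more template and 1 cycle corresponds to about a 2-fold difference if the product doubles in each cycle. Amplification efficiency per assay is not given in the sources used here. Per the file headers, the plates were read with SDS software under a manual fluorescence threshold of 0.2 and an automatic baseline. The deposited Ct values were raw, with no normalization. The file headers also carry the run day: the control plates were run on 2 days (replicate 1 on the first, replicates 2 and 3 on the second) and the 3 NOD1 plates on 1 later day, with no day shared by the groups.

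A second deposited table held the authors' comparison. It gave a delta Ct per group on a log2-like scale, per the file headers the Ct of a gene minus the average Ct of housekeeping genes, and the deposited ratio or fold of NOD1 over control computed from it. It also held a p-value deposited by the authors without a named test, and a signed fold score, which the authors deposited as the ratio where above 1 and as minus its inverse otherwise. Recomputing that table from the plates gave the same delta Ct for all 326 genes, to within a millionth of a cycle, when Ct values above 35 or undetermined were set to 35 and the mean Ct of ACTB, GAPDH and Tuba1 was subtracted. The deposited p-values matched those of an equal-variance test on the delta Ct for 326 of 326 genes, to within a relative difference of 1e-04. The authors' table gives group means only, so its alternative rests on the deposited p-values.

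For the analysis here, Ct values above 35 or undetermined were set to 35. The relative level of a gene was the mean Ct of ACTB, GAPDH and Tuba1 on the same plate minus the Ct of the gene, a log2-like scale on which higher means more transcript. A gene was kept when its Ct was under 35 in all 3 plates of at least 1 group, which kept 319 genes and dropped 7. The groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 over all 6 plates, with Benjamini-Hochberg adjustment and a threshold of adjusted p under 0.05. Errors of single values are SDs over 3 plates, and errors of differences are the standard errors (SE) of the limma fit. All adjusted p-values of genes come from this fit unless another is named. The reference genes were also compared on raw Ct with an exact permutation test, for which 3 plates against 3 cannot give a p below 0.1.

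Gene symbols are those of the plate layout. Of the 326 genes, 215 were matched to a current zebrafish gene by accession, 48 by symbol and 39 by synonym in a RefSeq gene table of assembly GRCz12tu, and 24 were not matched, among them CCL-C25y-like, CCL-Cub, IRAK2, LGP2, C3-1, C4-1 and 18S rRNA. 16 gene lists were written before the data were examined, and 11 of them had 5 or more kept members and were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Camera sets a list against the other genes of the plate, which was itself a panel chosen around immunity and signalling. Genes named in the text followed a rule set at the same time. They are nod1 and the reference genes, the 12 genes with the largest difference in each direction among those past the threshold whose NOD1 values all lay on 1 side of the control values, and the 3 members of each list with the largest absolute difference. A gene that this rule selects is not reported here. Other genes are named as examples within a list or group and were chosen after their values were seen.

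The script was tested on simulated data made from the levels and spreads of the 319 genes, with 80 genes changed in each of 20 runs. For the comparison of NOD1 with control it recovered 78.4% of genes changed by 1 and 92.6% of genes changed by 2 on the log2 scale, and 3.77% of calls were false. The simulated errors were normal and independent between genes, with no ceiling, no shift of the reference genes and no difference between run days. These rates therefore check the script and do not describe the calls made on the real plates. Alternatives set before the data were examined covered the scaling (global mean, global median, quantile, B2M added, each reference gene alone, raw Ct), the ceiling, the filter, the variance model, the replicate block, each plate left out in turn, the threshold, the list test and the authors' table. Added after the data were seen were a cyclic loess scaling, 18S rRNA as a further reference, removal of 8 wells lying more than 3 cycles from both other wells of their group, and the run day as a random block. The genomic DNA control wells, the blank and the other control wells entered no gene comparison.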

Results

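The series asked how the transcripts of immune and signalling genes differ between embryos given a NOD1 expression plasmid and embryos given the parent plasmid. NOD1 is an intracellular receptor of the NLR family that senses fragments of bacterial peptidoglycan. Each group had 3 plates. Between 314 and 321 of the 326 gene wells on a plate had a Ct under 35, and 1 to 3 were undetermined. The median Ct was 26.4 ± 0.118 (SD, n = 3) in the control group and 26.5 ± 0.051 in the NOD1 group. All 3 genomic DNA control wells of every plate stayed without a Ct. The positive PCR control wells had a mean Ct of 18.04 ± 0.233 in control and 18.14 ± 0.114 in NOD1 plates (n = 3 each; exact permutation p = 0.6, two-sided).

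The nod1 transcript was higher in every NOD1 plate. Its Ct fell from a mean of 28.5 in control to 20.6 in NOD1 embryos, and its level relative to the reference genes was 8.59 ± 0.42 (SE) higher on the log2 scale, a 386-fold difference (n = 3 per group, limma adjusted p = 2.25e-04). The authors' deposited table gives the same fold, 386. The relative level was -10.81, -10.94 and -10.97 in the control plates and -3.20, -1.49 and -2.26 in the NOD1 plates. The assay does not separate the plasmid-borne from the endogenous transcript. No well measured nod1 without reverse transcription, so plasmid DNA carried over with the RNA was not tested for.

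Among the 319 genes tested, 118 were higher and 49 were lower in NOD1 embryos, and 152 did not pass the threshold. After nod1, the largest rise was that of the chemokine CCL-C25y-like, by 6.43 ± 1.22 (SE) on the log2 scale or 86.3-fold (adjusted p = 0.00761), with 1 control well, that of replicate 1, more than 3 cycles later than the other control wells. Without that plate the rise was 5.07 (33.5-fold, adjusted p = 0.00415), and without control replicate 3 it was 7.40 (168-fold, adjusted p = 0.00924). The chemokine CXCL12a, a ligand of CXCR4 that guides migrating cells, rose by 3.83 ± 0.48 (14.2-fold, adjusted p = 0.00213), although a second assay on the plate that maps to the same gene by synonym, SDF1a, differed by 0.021 ± 0.16 (adjusted p = 0.925). The chemokine CCL-Cub was at the ceiling of 35 cycles in all 3 control plates and, relative to the reference genes, was at least 12.1-fold higher in NOD1. That bound holds for this scaling only, since the fold was 3.16 with cyclic loess and 3.22 with quantile scaling, where it did not pass (adjusted p = 0.0668). Rises of 8.08-fold to 11.01-fold were seen for the type I interferon IFNphi3, the Toll-pathway kinase IRAK2, the interferon-induced GTPase GBP1, the interferon gene ifng1-1, the cytokine receptor IL12RB2, lymphotoxin LTA, the homing receptor CCR7 and the cytokine IL17A/F1. For IL17A/F1, 2 of the 3 control wells were at the ceiling, so its fold is a lower bound for this scaling. The symbols CCL-C25y-like, CCL-Cub and IRAK2 were not matched to a current zebrafish gene, and these genes are described by the plate's symbols. Single plates moved some of these rises by over 1.5 times. IFNphi3 was 17.2-fold higher without control replicate 1 and 7.25-fold without control replicate 2, and without control replicate 3 IRAK2 was 6.54-fold and ifng1-1 5.73-fold higher. GBP1 was 6.07-fold higher without control replicate 2 and 17.2-fold without NOD1 replicate 3. The GBP1 call was lost when control replicate 2 (adjusted p = 0.0583), NOD1 replicate 1 (0.0859) or NOD1 replicate 2 (0.0827) was left out.

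The 12 largest falls were smaller. The 18S rRNA fell by 1.95 ± 0.15 on the log2 scale (adjusted p = 6.82e-04). CSF2RB, a shared receptor subunit of myeloid growth factors, fell by 1.84 ± 0.57 (adjusted p = 0.0409), a call lost when any single plate other than NOD1 replicate 3 was left out (adjusted p = 0.0715 to 0.119), with a ceiling of 40 cycles (-3.50, adjusted p = 0.153), and with values over 35 missing (-1.49, adjusted p = 0.0887). The well of NOD1 replicate 2 was undetermined and had been set to the ceiling. Without NOD1 replicate 3 it fell by 2.50 (adjusted p = 0.00260). SMAD3b, a mediator of TGF-beta signals, fell by 1.45 ± 0.16 (adjusted p = 0.00150), and the Toll-like receptor TLR18 fell by 1.40 ± 0.15 (adjusted p = 0.00135). IL6ST, the signal-transducing chain of the IL-6 receptor family, decreased by 1.35 ± 0.28 (adjusted p = 0.0104). The other 7 were the JNK-family kinase MAPK10, the costimulatory receptor CD40, the macrophage growth factor receptor CSF1R, the prolactin receptor PRLR, the apoptosis executioners CASP3b and CASP3a, and STAT5.1, at -1.31 to -1.11 on the log2 scale. The STAT5.1 call was lost without control replicate 1 (adjusted p = 0.0611), control replicate 2 (0.0627), NOD1 replicate 1 (0.0598) or NOD1 replicate 3 (0.0586).

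**Figure D1:**
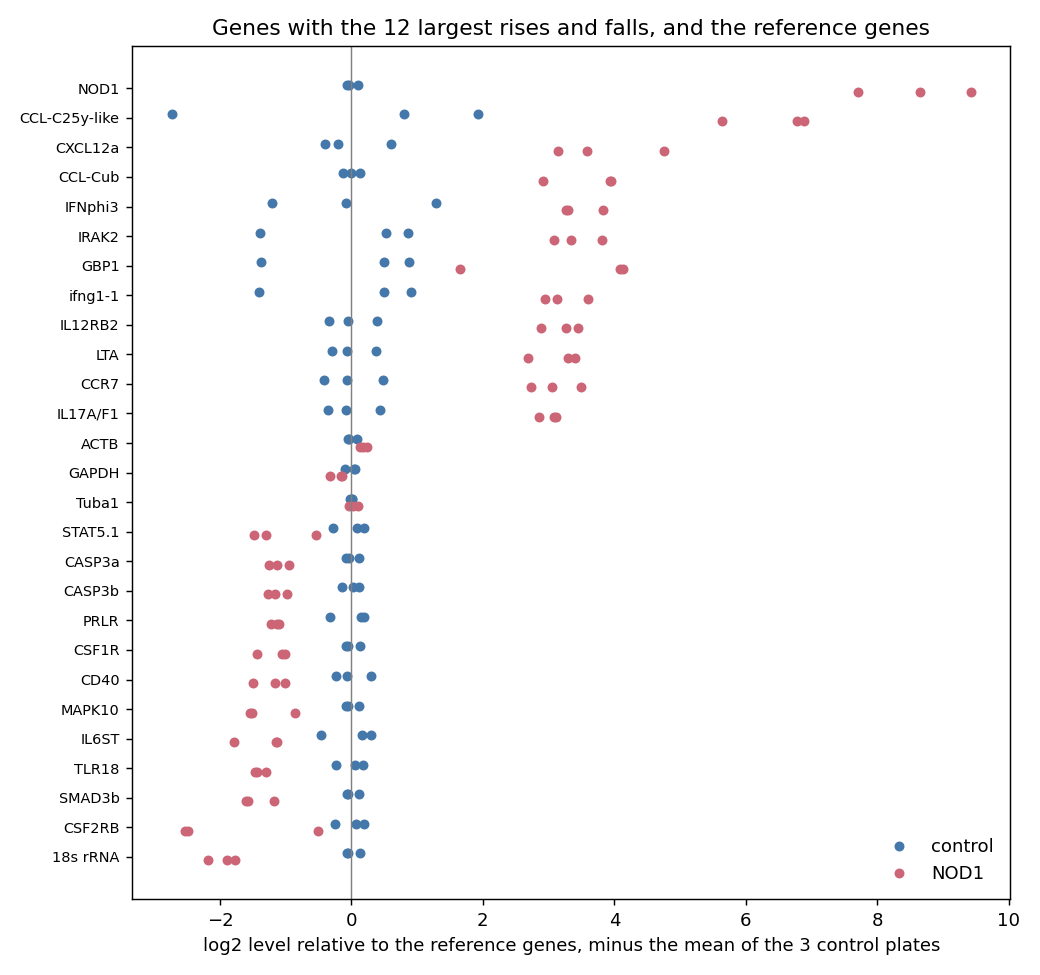
Each row is a gene and each point a plate, blue for the 3 control and red for the 3 NOD1 plates, drawn as the log2 level relative to the reference genes minus the gene's mean in the control plates. The 12 genes with the largest rises are headed by NOD1 at 8.59, and the 12 with the largest falls end with 18S rRNA at -1.95. Both sets were drawn only from genes past the threshold with no overlap between the groups.

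The higher share of calls depended on the scaling. With the reference genes the median difference of all 319 genes was 0.32 on the log2 scale. It was 0.43 with B2M added and 0.80 with 18S rRNA added, and it was -0.29 with the global mean, -0.16 with the global median, -0.091 with quantile, -0.024 with cyclic loess scaling and -0.34 on raw Ct. Against 118 higher and 49 lower genes, the global mean gave 76 and 140, the global median 81 and 113, quantile scaling 59 and 78, cyclic loess 66 and 72, and raw Ct 71 and 134. Adding 18S rRNA gave 195 and 18, ACTB alone 102 and 72, and GAPDH alone 127 and 26. Of the 12 largest rises, 9 passed the threshold under all 8 scalings compared, the exceptions being CCL-Cub, IRAK2 and GBP1. Of the 12 largest falls, 9 did so, the exceptions being 18S rRNA, CSF2RB and STAT5.1, and none of the 24 genes passed in the opposite direction under any of these scalings. Sizes moved as well under some scalings. The global mean and raw Ct moved all 167 called genes by over 1.5 times, all by the same amount, quantile scaling moved 98 and cyclic loess 88. With the global median, B2M added or 18S rRNA added, 0 of the 167 moved that far. Calls still changed there, with 81 of the 118 higher calls kept under the global median and 18 of the 49 lower calls with 18S rRNA added. With cyclic loess CCL-C25y-like was 49.8-fold, IFNphi3 4.80-fold, ifng1-1 4.64-fold, IL12RB2 4.21-fold, CCR7 3.86-fold, IRAK2 3.17-fold (adjusted p = 0.0900), LTA 2.70-fold and IL17A/F1 2.09-fold higher, while CSF2RB, TLR18, CD40 and 18S rRNA differed by -3.68, -2.45, -1.98 and -0.27 on the log2 scale. With quantile scaling PRLR and CSF1R differed by -1.78 and -1.81. The groups did not overlap for 204 genes, 63.9% of those tested, where chance gives 10%. The control plates and the NOD1 plates were run on different days, months apart, so run and group cannot be told apart.

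The reference genes themselves were later in NOD1 plates. The mean Ct of ACTB, GAPDH and Tuba1 was 17.6 ± 0.136 (SD, n = 3) in control and 18.3 ± 0.102 in NOD1, a difference of 0.655 cycles (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). On raw Ct, ACTB was later by 0.472, GAPDH by 0.867 and Tuba1 by 0.626 cycles (limma adjusted p = 0.0334, 0.00431 and 0.00751). B2M was later by 1.12 cycles (adjusted p = 0.0172) and 18S rRNA by 2.60 cycles (adjusted p = 2.35e-04). Relative to their own mean, ACTB differed by 0.18 (adjusted p = 0.199), GAPDH by -0.21 (0.182) and Tuba1 by 0.029 (0.830). Subtracting their own mean ties these differences together, so they cannot show that the reference genes were stable. On this scale the groups did not overlap for ACTB and GAPDH and did overlap for Tuba1.

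Of 43 kept members of the list of chemokines and their receptors, 28 were higher, 0 were lower and 15 did not pass, with the same counts, 28 and 0, adjusted over the list alone. The mean difference of the list exceeded that of the other genes by 0.89 on the log2 scale (camera adjusted p = 5.48e-04; adjusted p = 0.487 with an estimated correlation). Besides the members named above, the receptor CCR9b was 2.71 higher on the log2 scale (adjusted p = 0.00220). Its mean control delta Ct was 17.25, where CCL-Cub, at the ceiling in all 3 control plates, had 17.39. The control wells of CCR9b thus lay at or close to the ceiling, which limits the size of its rise. The list was weakly expressed, with a mean control Ct of 29.0. Its counts of higher and lower members were 20 and 6 with the global mean, 9 and 3 with quantile and 10 and 2 with cyclic loess scaling.

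Of 40 kept members of the list of inflammatory cytokines and receptors, 26 were higher, 4 were lower and 10 did not pass, and 26 and 4 when adjusted over the list alone. The mean exceeded that of the other genes by 0.71 (camera adjusted p = 0.0114; adjusted p = 0.754 with an estimated correlation). IL12RB2 was 9.15-fold, LTA 8.77-fold and IL17A/F1, for this scaling, at least 8.08-fold higher. With values over 35 missing, where its 2 control wells at the ceiling drop out, IL17A/F1 was 5.97-fold higher. The classical inflammatory cytokines tnfa and IL1B rose by 2.59 and 1.62 on the log2 scale. The 4 lower members were TNFRSF21, MIF, CSF1R and IL6ST. The mean control Ct of the list was 28.7. Higher and lower members numbered 20 and 7 with the global mean, 13 and 7 with quantile and 15 and 7 with cyclic loess scaling.

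Of 36 kept genes of the interferon list, 19 were higher, 0 were lower and 17 did not pass, with 19 and 0 adjusted over the list alone. The list mean exceeded that of the other genes by 0.58 (camera adjusted p = 0.0114; adjusted p = 0.487 with an estimated correlation). IFNphi3 rose by 3.46 ± 0.63, GBP1 by 3.29 ± 0.90 and ifng1-1 by 3.22 ± 0.62 on the log2 scale, and the antiviral GTPase MX rose by 1.71. MX was weak in control plates, with a mean delta Ct of 16.6 against 17.4 for a gene at the ceiling (CCL-Cub). Among the interferon regulatory factors, IRF4b, IRF2, IRF3, IRF8 and IRF10 rose by 2.59, 1.13, 1.11, 0.97 and 0.76 (adjusted p = 0.0160, 0.00154, 0.0223, 0.00451 and 0.00969), and IRF4b by 3.20 without control replicate 2 and 1.94 without control replicate 3. IRF1, IRF7 and IRF9 differed by 0.088, -0.14 and 0.18 and did not pass. The mean control Ct of the list was 28.0. Higher and lower members numbered 12 and 8 with the global mean, 8 and 2 with quantile and 11 and 2 with cyclic loess scaling.

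Of 24 kept members of the MAP kinase and AP-1 list, 4 were higher, 5 were lower and 15 did not pass, against 3 and 4 adjusted over the list alone. The list mean was -0.92 relative to the other genes (camera adjusted p = 0.0114; adjusted p = 0.754 with an estimated correlation). MAPK10 fell by 1.31 ± 0.22, whereas JUNB, a subunit of the AP-1 transcription factor, rose by 1.41 ± 0.19. MAP2K6 had the largest difference, -3.92 ± 3.16, from 1 NOD1 well at the ceiling, and did not pass (adjusted p = 0.329). The median difference of the list was -0.23, and its mean includes MAP2K6. The mean control Ct of the list was 24.1, and the 80 genes of the plate with the lowest mean Ct had a median difference of -0.11. Whether the list differs from genes of similar Ct was not tested. Higher and lower members numbered 2 and 18 with the global mean, 3 and 6 with quantile and 3 and 5 with cyclic loess scaling. With quantile and cyclic loess scaling, camera passed none of the 11 lists (3 and 2 at an unadjusted p under 0.05). With 18S rRNA added it also passed none (2 at an unadjusted p under 0.05), on raw Ct the interferon list did not pass (adjusted p = 0.0533), and with an estimated correlation no list passed (0 at an unadjusted p under 0.05). With 18S rRNA added and on raw Ct the difference of a list mean from the other genes was as large as with the reference genes, since these scalings move all genes alike.

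**Figure D2:**
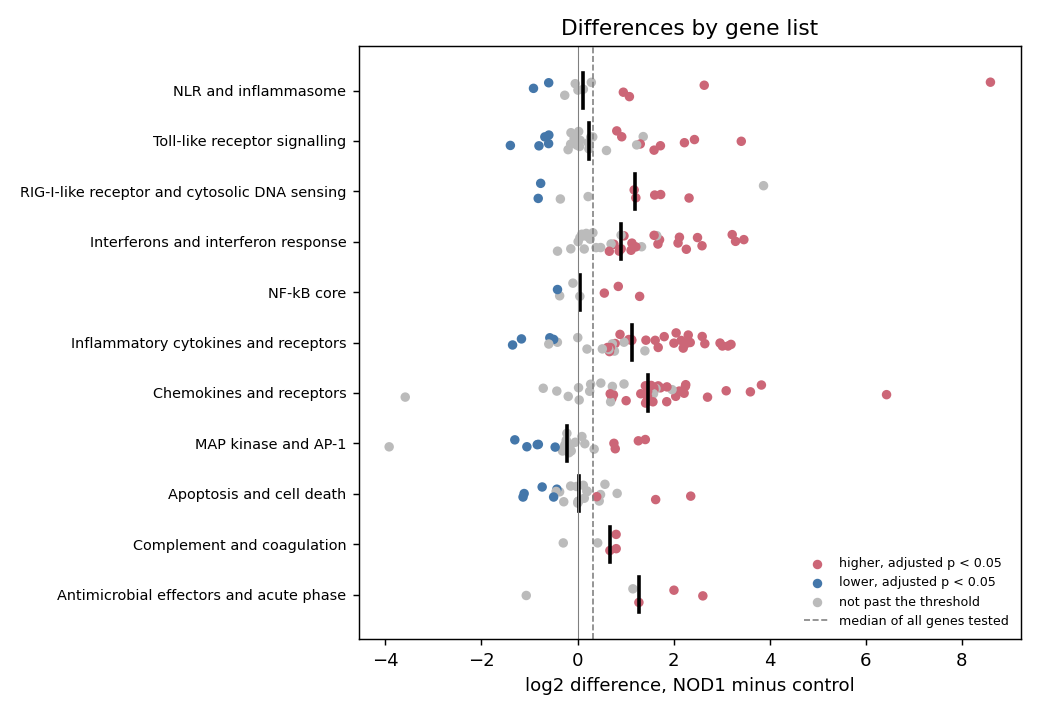
Each point is a gene, placed by its log2 difference (NOD1 minus control) in the row of its list, red if higher, blue if lower and grey if not past the threshold, with a black bar at the list median and a dashed line at the median of all genes, 0.32. The chemokine list has 28 red and 0 blue points, and the MAP kinase list 4 red and 5 blue.

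In the list of NLR and inflammasome genes, 4 of 11 members were higher, 2 were lower and 5 did not pass, with 4 and 2 adjusted over the list alone. Besides nod1, NLRC5, an interferon-inducible regulator of MHC class I genes, rose by 2.64 ± 0.25 on the log2 scale, and by 1.61 with cyclic loess scaling. NOD2, a related peptidoglycan sensor, rose by 1.08 ± 0.13, although NOD2 was -0.091 with quantile scaling (adjusted p = 0.345). RIPK2, the kinase that relays NOD1 and NOD2 signals, fell by 0.92. The list mean exceeded that of the other genes by 0.48 while camera's direction was down (adjusted p = 0.993; also 0.993 with an estimated correlation). Without nod1, the injected gene itself, 3 of 10 members were higher and 2 lower, and the list mean was -0.27 relative to the other genes. Higher and lower members, nod1 included, numbered 3 and 5 with the global mean, 2 and 3 with quantile and 2 and 2 with cyclic loess scaling.

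Toll-like receptor genes went both ways, with 8 of 28 higher, 5 lower and 15 not past the threshold (7 and 3 adjusted over the list alone; camera adjusted p = 0.956), and with 5 higher and 15 lower under the global mean, 3 and 8 under quantile and 3 and 7 under cyclic loess scaling. TLR4bb was 5.40-fold and TLR8a 4.67-fold higher, and the adaptor MYD88 differed by 0.023 (adjusted p = 0.904). On the log2 scale TLR4bb rose by 2.43 and TLR8a by 2.22, against 2.04 and 1.30 with cyclic loess scaling. Among RIG-I-like receptor and DNA-sensing genes, 5 of 10 were higher and 2 lower (5 and 2 adjusted over the list alone; camera adjusted p = 0.851), against 3 and 4 with the global mean, 3 and 3 with quantile and 4 and 3 with cyclic loess scaling. The viral RNA sensor RIG-I rose by 2.32 ± 0.26 and the related LGP2 by 1.73 ± 0.20 on the log2 scale (adjusted p = 0.0834 for LGP2 with quantile scaling), and the kinase TBK1 rose by 1.61. TRADD differed by 3.87 ± 2.32 and did not pass (adjusted p = 0.207), with a late well in control replicate 3. Without that plate it was 1.09 higher (adjusted p = 0.0152).

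Of 7 genes of the NF-kB core, 3 were higher and 1 lower (3 and 1 adjusted over the list alone; camera adjusted p = 0.851), against 0 and 4 with the global mean and 1 and 3 with quantile and with cyclic loess scaling. BCL3 rose by 1.29 ± 0.35, the inhibitor NFKBIA by 0.85 ± 0.17 and NFKB1 by 0.56 ± 0.17. With the global median none of these 3 passed (adjusted p = 0.0606, 0.133 and 0.682), and NFKB1 was -0.67 with quantile scaling (adjusted p = 0.0268). The BCL3 call was also lost without control replicate 1 (adjusted p = 0.0692), control replicate 3 (0.0721), NOD1 replicate 2 (0.0792) or NOD1 replicate 3 (0.0620), and the NFKB1 call without any of 4 plates (control replicates 1 and 2, NOD1 replicates 2 and 3; adjusted p = 0.104 to 0.118).

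Among 25 genes of apoptosis and cell death, 3 were higher and 5 lower (3 and 4 adjusted over the list alone; camera adjusted p = 0.184; adjusted p = 0.754 with an estimated correlation). With the global mean 2 were higher and 14 lower and camera passed the list, in the direction down (adjusted p = 0.0474; adjusted p = 0.211 with an estimated correlation), and with quantile and with cyclic loess scaling 2 were higher and 7 lower. The death ligand FASLG was 5.12-fold higher, or 2.36 on the log2 scale, and 1.07 higher with cyclic loess scaling. CASP3b fell by 1.13 ± 0.14 on the log2 scale. Of 5 complement and coagulation genes, 3 were higher and 0 lower, adjusted over the list alone as well (camera adjusted p = 0.851, direction up, while the list mean was -0.13 relative to the other genes). Counts were 0 and 1 with the global mean, 0 and 2 with quantile and 0 and 0 with cyclic loess scaling. C4-1 and C3-1 differed by 0.80 each and C4-2 by 0.67. With the global median none of the 3 passed (adjusted p = 0.197, 0.190 and 0.403), and C4-1 and C4-2 were -0.51 and -0.26 with quantile scaling (adjusted p = 0.0452 and 0.271). The calls of C4-1 and C4-2 were lost when single plates were left out (adjusted p = 0.0888 to 0.0945 for C4-1 in 4 of the 6 cases, 0.0581 to 0.0805 for C4-2 in 5 of the 6).

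Of 5 antimicrobial and acute phase genes, 3 were higher and 0 lower, adjusted over the list alone as well (camera adjusted p = 0.469). The peptidoglycan recognition protein PGRP6 was 6.09-fold and the iron-regulatory peptide hamp1 4.02-fold higher, although a second assay in the list that maps by synonym to the same gene as hamp1, hamp2, differed by -1.07 ± 0.95 on the log2 scale (adjusted p = 0.373). PGRP2 was 2.42-fold higher, a call lost without control replicate 2 or 3 or any single NOD1 plate (adjusted p = 0.0626 to 0.111), and its difference was -0.064 with quantile scaling and not past the threshold with the global median (adjusted p = 0.180).

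The remaining lists had too few members on the plate for a test. AKT1 differed by 0.27 (adjusted p = 0.0825), PSME1 by 0.94 (0.506), B2M by -0.46 (0.215), CD40LG by 1.06 (0.112) and GATA3 by 0.32 (0.138), and none passed. SPI1 and CSF1R were the only members of the list of other cell types on the plate. SPI1 rose by 0.81 ± 0.19 (adjusted p = 0.0146; 0.0507 without control replicate 3 and 0.132 with the global median) and CSF1R fell by 1.17 ± 0.16 (adjusted p = 0.00271). Outside that list, and chosen after the values were seen, PTPRC, carried by leukocytes, differed by -0.011 ± 0.14 (adjusted p = 0.953), and EPOR, the erythropoietin receptor, fell by 1.01 ± 0.16 (adjusted p = 0.00411). No autophagy gene of the list was on the plate.

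**Figure D3:**
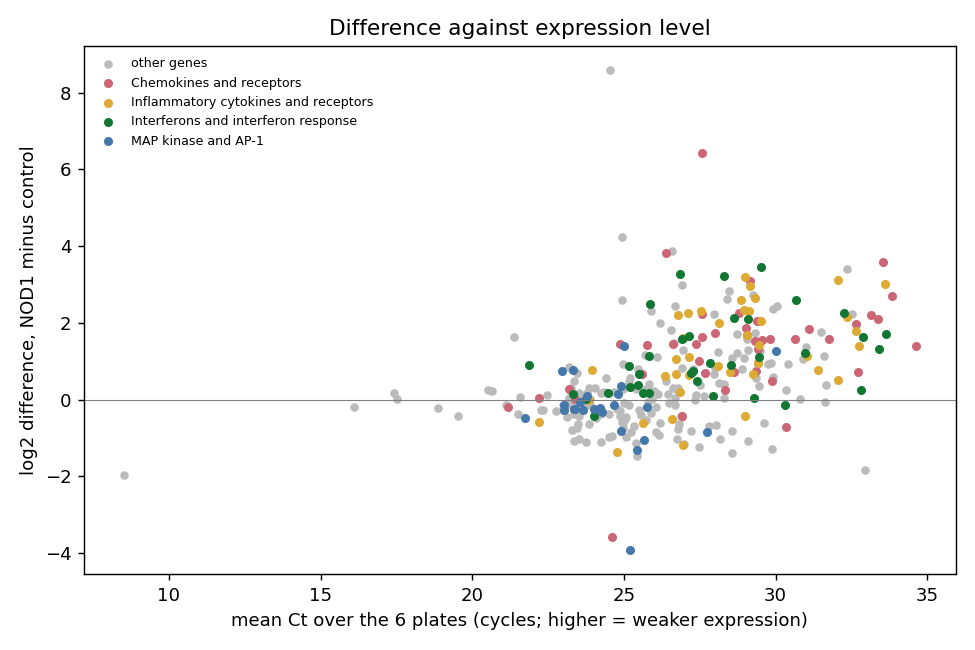
Each point is a gene, with its mean Ct over the 6 plates on the horizontal axis (cycles, higher is weaker expression) and its log2 difference, NOD1 minus control, on the vertical axis, coloured by list. Among the 80 genes with the highest mean Ct 50 were higher and 2 lower, and among the 80 with the lowest 9 were higher and 15 lower.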

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

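The cyclic loess, 18S rRNA, single-well and run-day settings were chosen after seeing the data. The difference of nod1 kept its direction and its side of the threshold under all 21 alternatives, at 7.94 to 9.08 on the log2 scale, and the mean Ct of the reference genes was later in NOD1 with each of the 6 plates left out in turn and with B2M added, by 0.588 to 0.770 cycles. Higher and lower genes numbered 76 and 140 with the global mean, 81 and 113 with the global median, 59 and 78 with quantile scaling, 71 and 134 on raw Ct, 66 and 72 with cyclic loess, 195 and 18 with 18S rRNA added, and 127 and 26 with GAPDH alone. With the global mean, all 76 higher genes were among the 118. With quantile scaling 3 of the 118 were called lower, and with cyclic loess also 3. Lower genes numbered 17 with a fold of 2 or more required and 24 at adjusted p under 0.01. Leaving out 1 plate gave 96 to 113 higher and 31 to 45 lower genes, with 31 without control replicate 1 and 32 without control replicate 3, where fewer plates were compared. The authors' deposited p-values gave 125 higher and 57 lower genes at p under 0.05 and 104 and 43 after Benjamini-Hochberg adjustment. The ceiling, filter and variance settings gave 100 to 119 higher and 47 to 56 lower genes. Without the 8 late wells they numbered 123 and 50, and TRADD and PSME1 then passed.

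The number of lists past the threshold was 4, and 0 with quantile scaling, cyclic loess, 18S rRNA added or an estimated correlation, and 7 with fry, which does not set a list against other genes. With 18S rRNA added, 2 lists had an unadjusted camera p under 0.05. Of the 52 genes under the naming rule other than nod1, 9 lost a call when some plate was left out and 4 gained one (TRADD, PSME1, B2M and GATA3). Genes that changed sign did so under scalings. With the global mean ACTB was -0.43, Tuba1 -0.58, NFKB1 -0.052, AKT1 -0.34 and GATA3 -0.29. With the global median ACTB was -0.29, Tuba1 -0.45, AKT1 -0.21 and GATA3 -0.16. With quantile scaling Tuba1 was -0.037, NOD2 -0.091, NFKB1 -0.67, PSME1 -0.29, C4-1 -0.51, C4-2 -0.26, PGRP2 -0.064 and CD40LG -0.27. On raw Ct ACTB was -0.47, Tuba1 -0.63, NFKB1 -0.098, AKT1 -0.39 and GATA3 -0.34. With cyclic loess Tuba1 was -0.054, NFKB1 -0.62, PSME1 -0.46, C4-1 -0.30, C4-2 -0.24 and CD40LG -0.44. With 18S rRNA added GAPDH was 0.28 and B2M 0.026. Apart from scalings, Tuba1 changed sign without NOD1 replicate 2, its range with 1 plate left out being -0.0051 to 0.061. Quantile scaling fixed 18S rRNA, first in rank on each plate, at 0. The global mean, the global median, raw Ct and added reference genes shift all genes alike, and leaving out plates makes the samples smaller. Quantile and cyclic loess scaling move genes unequally, and for them, as otherwise, the cause was not tested.

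With the replicate block, 111 genes were higher and 40 lower, 107 and 39 of them shared with the unblocked fit. GBP1, NFKB1 and C4-2 did not pass there (adjusted p = 0.0549, 0.0528 and 0.0611). Deviations of plates with the same replicate number correlated at 0.11, 0.03 and -0.02, and not every plate correlated best with its own number. These values gave no support for pairing but cannot exclude it, and the labels do not say whether the numbers pair the plates. With the run day as a random block, 141 were higher and 71 lower, at an estimated correlation of -0.33 that rests on the control days alone and narrows the errors. Values near the ceiling of 35 cycles limit weakly expressed genes.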

Other observations

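The gene families, the comparison with control wells, including the demand that these wells reach the Ct range of the trend, and the pairs of assays below were chosen after the values were seen, and the other tests of level and of lists were set before their results were seen. Genes of the STAT family, transcription factors downstream of cytokine receptors, went both ways. STAT1b and STAT2, which act in interferon signalling, rose by 2.12 ± 0.44 (SE) and 1.59 ± 0.38 on the log2 scale (limma adjusted p = 0.00969 and 0.0158), while STAT3, STAT5.1, STAT5.2, STAT6 and STAT7 fell by 0.98, 1.11, 1.03, 0.97 and 0.85 (the last 2 assays map to the same gene). Of 9 STAT assays of 8 genes, 2 were higher and 5 lower (4 genes), and 2 and 5 assays with the global mean and cyclic loess scaling, and 0 and 5 with quantile scaling. All 4 genes of the IL17 family and its receptor rose when scaled to the reference genes. IL17A/F1 rose by at least 3.01 for this scaling (2 of 3 control wells at the ceiling), IL17C by 1.42, IL17D by 1.07 and IL17RD by 0.78. Under the global mean, quantile and cyclic loess scaling, 3, 2 and 3 were higher and past the threshold.

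Of 6 SMAD genes, 3 were lower (SMAD3b, SMAD2 and SMAD3a, at -1.45, -0.63 and -0.59), and 6, 3 and 3 with the global mean, quantile and cyclic loess scaling. These calls carry the same confounding of run day with group as all others.

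The difference between the groups depended on expression level. The SD of Ct across genes was 3.79 ± 0.028 (n = 3) on control plates and 3.26 ± 0.029 on NOD1 plates (exact permutation p = 0.1, the smallest possible), and Spearman's rho of the difference against mean level was -0.51 across 319 genes, which are not independent replicates (95% bootstrap interval -0.59 to -0.43). The ceiling of 35 cycles is argued against, since rho was -0.46 among the 278 genes with a mean Ct under 30 (interval -0.55 to -0.36). A response of the interferon, cytokine, chemokine, Toll-like, RIG-I-like, NLR and antimicrobial lists alone is argued against as the whole of it, only as far as genes vary independently. Outside those lists, rho was -0.23 among 149 genes (interval -0.39 to -0.05). All these intervals resample genes as if independent and carry no spread between plates. Genes of the NF-kB core and complement lists remained among the 149, so a wider immune response is not argued against. A change in amplification or plate reading stays open: the reverse transcription control wells were later by 0.322 cycles against a median of 0.791 for 15 genes of similar Ct, -2.42 combined standard errors apart, and the positive PCR control wells by 0.099 against 0.747 for 4 genes, -2.97 apart, but less RNA would move genes and not these wells, and no control well lies at the high Ct where genes were earlier. Run day and the plasmid cannot be told apart, so a broad rise of weakly expressed genes in NOD1 embryos may be either.

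The chemokine, cytokine and interferon lists held weakly expressed genes, so their rise could follow from level. They are the 3 lists that camera had passed upward on these same plates. A high percentile in the comparison below is therefore partly built in. Against 10000 lists drawn with replacement from the 15 genes nearest in mean Ct to each member, outside the 3 lists, the list median lay at percentile 100 for chemokines (1.46 against a typical 0.56 on the log2 scale), 99.11 for cytokines (1.13 against 0.51) and 99.82 for interferon genes (0.91 against 0.24). The drawn lists were slightly more strongly expressed, at a mean Ct of 28.25, 28.16 and 27.50 against 28.62, 28.40 and 27.79. The draws also treat genes as independent, while the estimated correlation within the lists was 0.075, 0.207 and 0.038. Low level alone is therefore argued against as the whole of the difference only as far as genes vary independently. The choice of lists on the same values weakens this further. Cyclic loess scaling, which takes out any trend with level including a real one, left the excess of the list mean over other genes at 0.37 for chemokines, 0.28 for cytokines and 0.34 for interferon genes, down from 0.89, 0.71 and 0.58, and ended the camera calls (adjusted p = 0.163, 0.248 and 0.169). In limma's moderated statistic, the excess went from 3.58, 2.79 and 1.90 to 1.80, 1.72 and 1.69. Its SD over the other genes was 4.91, 4.85 and 5.11 before and 5.12, 4.89 and 5.07 after. Camera tests a transformed form of this statistic, so these values are not the scores it compares. The cause of each lost call was not tested further. That NOD1 expression raises these lists beyond the general trend is a hypothesis, and the difference in run days stays open as another explanation, which these plates cannot test and plates of both groups run on a shared day would.

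The 6 plates can be split 3 against 3 in 10 ways, the real split being 1 of them, too few for a share under 0.05. The real split gave 167 genes past the threshold and the highest of the others 0 by limma (7 at an unadjusted p under 0.05). For gene lists, the real split gave 4 past the camera threshold and the highest of the others 3.

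Several pairs of assays map to the same gene, with an assay of each pair matched by synonym only, so a shared target is not certain. CXCL12a and SDF1a had mean Ct values of 28.0 ± 0.635 and 23.1 ± 0.097 (SD, n = 3) in control and 24.8 ± 0.853 and 23.7 ± 0.193 in NOD1 plates, so that their log2 differences lay 3.81 apart (exact permutation p = 0.1, the smallest possible). The assays hamp1 and hamp2 lay 3.07 apart and TLR4a and TLR4ba 0.86 apart (exact permutation p = 0.1 for each), while IL-6RA and IL6R lay 0.26 apart (exact permutation p = 0.5). STAT6 minus STAT7 was only -0.12, also with an exact permutation p of 0.1, so this p does not measure the size of a gap. CXCL12b minus SDF1b was -3.62, with an undetermined CXCL12b well in NOD1 replicate 3. Of the 8 wells more than 3 cycles from both others of their group, JAK1 in control replicate 1, EDG2 in control replicate 2 and CXCL12b in NOD1 replicate 3 were undetermined although the other wells had a Ct between 22.45 and 24.62. In the authors' deposited table JAK1 has a fold of 18.9 with a p of 0.363.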
